A study of Danio rerio with 47 samples.

How the data were processed

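Total RNA of developing zebrafish trunks was amplified and hybridized to 1-colour NimbleGen arrays with the dye Cy3, per the labels. The authors' deposited table holds 1 log2 value per row and array for 47 arrays and 31475 rows. The submitters' processing notes name RMA (background correction, quantile normalization and median polish), and its version is not given in the sources used here. Arrays have no read depth, so the number of arrays limits the precision. The labels call the arrays biological replicates without saying whether each carries 1 fish or a pool, and nothing beyond the labels shows that the samples are separate. The labels of the morphants at 14 dpf state 10 replicates, of which 9 arrays were at hand.

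Groups came from the labels: dnd morphant and wild type, at 14 and 22 dpf. Row names are older gene symbols or clone names. They were paired with current symbols through reference tables of zebrafish genes, which matched 22574 rows, while 8815 had no match and 86 matched several genes. A gene with more than 1 row, of which there were 983, was represented by the row with the highest mean over all arrays.

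Equal values below 3.7 were counted between arrays, because quantile-normalized arrays of one run share exact values. There were 10 equal values between arrays of 14 dpf (0.05 by chance), 53 between arrays of 22 dpf (2.72 by chance) and 2 between arrays of different age (1.46 by chance). The ages were therefore taken as normalized in separate runs, and the comparisons of 22 with 14 dpf within a genotype, which had been intended, are given as group levels without a test. Counts of those comparisons had been seen in a first look at the data. Between title numbers 1 to 12 and 13 onward within an age there were 6 (0 by chance) and 23 (1.3 by chance) equal values. These number groups were used as a possible batch because title numbers are the only order the labels give.

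Deviations of each array from its group mean, over rows with a mean of at least 8, were correlated between arrays of a group. Of 263 pairs 6 had a correlation above 0.65, between 0.765 and 0.92, and the highest of the other pairs had 0.534. All arrays were kept in the reported values, and p values may then be too small if a pair holds the same fish or the same RNA. Values with these pairs averaged (41 samples: 8 and 14 at 14 dpf, 8 and 11 at 22 dpf, morphants first) are given for counts of rows, for some lists and for named genes that lost their call. This choice was made after the data and both counts had been seen. Counts of list members are for all arrays unless stated, and several were lower with the pairs averaged.

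The comparisons were fitted with limma 3.58.1 in R 4.3.3 on a model of the 4 group means, with 43 residual degrees of freedom (37 with the pairs averaged), eBayes, and Benjamini-Hochberg adjustment over all rows, called at an adjusted p below 0.05. No filter on low values was used. Contrasts were morphant minus wild type at each age, the difference of these effects (22 minus 14 dpf), and the overlap of the calls against the number chance gives.

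The 28 gene lists, written before the data were examined from textbook knowledge, held 588 measured members, 16 of them in more than 1 list. The score of a list is the mean log2 value of its members on an array, for lists with at least 5 measured members. Scores were compared by a two-sided permutation test, exact at 14 dpf and with 1e+05 resamples at 22 dpf, adjusted over the lists of a comparison. Differences of list effects between ages were tested with limma on the scores. Camera, with a preset correlation of 0.01 and with an estimated one, and fry were run beside them. The spread of 5 lists was compared as the mean absolute deviation from the group median by a permutation test.

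Genes are named by a rule written before the data were examined: the 10 largest rises and the 10 largest falls among called rows with a gene name, up to 4 members of each list with the smallest p, and 16 germ cell and gonad genes in both morphant comparisons. From these the text gives those that belong to a described group or lead a comparison, picked after their values had been seen.

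The analysis was tested on simulated data. Values drawn from a normal distribution with each row's mean and spread received changes in some rows of the morphant arrays. At 14 dpf 8.96%, 37.3% and 95.5% of rows changed by 0.5, 1 and 2 log2 units were called, with 7 false calls. At 22 dpf the shares were 10.4%, 50.7% and 84.8%, with 4 false calls. Rows and arrays were drawn independently, without near-duplicate pairs or correlation between genes, so these shares and false calls need not hold for the real arrays. For list scores of arrays shuffled within an age, 6.43% of 560 unchanged tests had a permutation p below 0.05 before adjustment, and 92.9% did when shifted by 1 unit. Several list differences called below were smaller than this shift, and the share called after adjustment was not computed.

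Alternatives were a filter on low rows, 3 other scalings, eBayes with trend and robust settings, array weights, fits of only the groups compared, a rank-sum test per row, the number groups as a block, scores of 4 tissues as covariates, the mean of all rows of a gene, z-scores, other set tests, another measure of spread, and leaving out each array. Chosen after seeing the data were averaging of the near-duplicate pairs, each number group alone, title number as a replicate block, and the alternatives for lists beyond the germ plasm, meiosis and oocyte lists, including each list's difference with each array left out. Rotations of the labels along the title numbers, within numbers 1 to 12 and 13 onward, were added then too. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.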

Results

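Gene expression was measured on 47 1-colour NimbleGen arrays of developing zebrafish trunks. The labels do not say whether an array carries 1 fish or a pool. The fish were wild type or dnd morphants, which had received a morpholino (an antisense oligonucleotide that blocks translation) against dnd at the 1-cell stage. The dnd protein binds RNA, and primordial germ cells need it to survive. The labels give the morphants a germ cell number of 1 to 9, scored at 24 hours post fertilization. There were 9 morphant and 14 wild-type arrays at 14 days post fertilization (dpf), and 10 morphant and 14 wild-type arrays at 22 dpf. The deposited values are log2 intensities for 31475 rows, and the median of an array lay between 7.27 and 7.70. The number of arrays limits the precision, and values near 5 lie close to the lower end of the scale, where no detection calls were at hand. Differences are morphant minus wild type on the log2 scale with their standard error (SE), and a number of arrays beside one counts the morphant arrays on that side of the wild-type median. Genes carry current symbols, with the name in the files where it differs.

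The transcript of the targeted gene, dnd1 (listed as dnd), was lower in morphants at 22 dpf. It averaged 5.58 ± 1.29 in morphants and 9.35 ± 2.03 in wild type at that age, a difference of -3.76 ± 0.61 (adjusted p = 2.78e-05, 10 of 10 arrays). At 14 dpf dnd1 averaged 6.01 ± 0.94 in morphants and 7.29 ± 1.39 in wild type, and its difference of -1.28 ± 0.63 did not pass (adjusted p = 0.295, 9 of 9 arrays). A morpholino of this kind blocks translation and leaves the transcript in place, so the level of dnd1 does not check the knockdown, and dnd1 is itself a germ cell transcript.

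The comparison at 14 dpf asked which transcripts differ in the trunk after early loss of germ cells, in a study whose title concerns testis formation. The germ cell lists were lower in morphants and the leukocyte list was higher. The score of the germ plasm and piRNA list, genes that act in germ plasm or in silencing transposons, averaged 6.40 ± 0.53 (SD, n = 9) in morphants and 7.82 ± 0.49 (SD, n = 14) in wild type. By an exact permutation test the difference was -1.42 (adjusted p = 0.000206), and 9 of 9 morphant arrays lay below the wild-type median. The meiosis list averaged 6.90 ± 0.23 (SD, n = 9) in morphants and 7.69 ± 0.34 (SD, n = 14) in wild type. Its difference was -0.78 (adjusted p = 0.000223, exact permutation test), and 9 of 9 morphant arrays lay below the wild-type median. The leukocyte list went the other way, with 8.68 ± 0.24 (SD, n = 9) in morphants and 8.18 ± 0.33 (SD, n = 14) in wild type. That is a difference of 0.50 (adjusted p = 0.0111, exact permutation test), and 9 of 9 morphant arrays lay above the wild-type median. For each of these lists camera gave an adjusted p = 0.0853 with an estimated correlation.

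For the germ plasm and piRNA list, of 20 measured members 0 rose, 11 fell and 9 did not pass. Of all 20 members, 1 rose and 14 fell when adjusted over the list alone. The falls included tdrd9 (-3.85 ± 0.59, adjusted p = 0.000148, 9 of 9 arrays) and tdrd1 (-1.86 ± 0.33, adjusted p = 0.00113), Tudor-domain proteins of the piRNA pathway, and pld6 (-2.12 ± 0.41), which acts in piRNA production. The RNA helicase ddx4 (listed as vasa), a standard germ cell marker, averaged 7.44 ± 1.46 in morphants and 10.28 ± 1.29 in wild type and fell by 2.84 (SE 0.57, adjusted p = 0.00426, 8 of 9 arrays). Dazl, an RNA-binding protein of germ cells, changed by -1.86 ± 0.31 and the Piwi protein piwil1 by -1.62 ± 0.36. Mov10l1 (listed as zgc:154086), a helicase of piRNA production, changed by -2.39 ± 0.49. The exception in the list was nanos3, a translational regulator of germ cells, which stood at 6.31 ± 0.65 in morphants and 5.39 ± 0.67 in wild type. Its difference was 0.92 ± 0.30 (adjusted p = 0.089), and it passed as a rise when adjusted over the list alone.

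For the meiosis list, of 24 measured members 0 rose, 4 fell and 20 did not pass. When adjusted over the list alone, 0 rose and 7 fell. The cohesin subunit smc1b had the largest fall of any named gene at this age, from 10.76 ± 0.79 in wild type to 6.12 ± 1.57 in morphants (-4.64 ± 0.56, adjusted p = 1.94e-06, 9 of 9 arrays). Hormad1, a protein of the meiotic chromosome axis, changed by -2.59 ± 0.47, the synaptonemal complex gene sycp2 by -1.83 ± 0.28 and the meiotic cohesin stag3 (listed as loc100333021) by -1.25 ± 0.32. Sycp3, of the same complex as sycp2, stood at 5.72 ± 0.39 in morphants and 6.44 ± 1.35 in wild type and did not pass (adjusted p = 0.461). The oocyte and egg coat list averaged 6.12 ± 0.24 (SD, n = 9) in morphants and 6.49 ± 0.25 (SD, n = 14) in wild type. Its difference was -0.37 (adjusted p = 0.0149, exact permutation test), and 8 of 9 morphant arrays lay below the wild-type median. It lost its call in camera, with adjusted p = 0.175 at the preset and adjusted p = 0.717 with an estimated correlation. Of its 26 measured members 1 fell and 0 rose, also when adjusted over the list alone. The member that fell was org, the oogenesis-related gene (-2.97 ± 0.59, 9 of 9 arrays). The oocyte genes figla (0.84 ± 0.56, adjusted p = 0.474), zp3 (-0.09 ± 0.68, adjusted p = 0.964), gdf9 (0.04 ± 0.36) and bmp15 (-0.21 ± 0.45) did not pass. Outside the lists, adad1 (listed as loc564818, -2.67 ± 0.52), the tubulin tuba7l (-2.55 ± 0.46), tfpil (listed as wu:fb59d01, -2.72 ± 0.44) and the avidin gene avd (listed as loc567678, -2.38 ± 0.68) were among the largest falls.

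Among the largest rises at 14 dpf, the chemokine gene ccl19a.2 (listed as zgc:194112) averaged 9.35 ± 3.13 in morphants and 5.72 ± 1.60 in wild type (3.63 ± 0.80, adjusted p = 0.00936, 7 of 9 arrays). Irg1l, an immune-responsive gene, averaged 8.94 ± 2.81 in morphants and 5.61 ± 0.63 in wild type (3.32 ± 0.66, adjusted p = 0.00349, 8 of 9 arrays). Mhc1zaa, of the class I histocompatibility complex, rose by 3.08 ± 0.75 (adjusted p = 0.0177, 9 of 9 arrays). Irf8, a transcription factor of macrophages, rose by 2.41 ± 0.36 (9 of 9 arrays), the chemokine ccl27a (listed as ccl1) by 2.27 ± 0.42, the interferon-induced mxc by 2.02 ± 0.49 and the cytokine il10 by 1.81 ± 0.45. For the leukocyte list, of 22 measured members 2 rose, 0 fell and 20 did not pass. Counts adjusted over the list alone were 3 rising and 0 falling. The rises were cd74b, the invariant chain of class II complexes (1.12 ± 0.27), and spi1b, a myeloid transcription factor (0.88 ± 0.24). Lysozyme, lyz, stood at 14.29 ± 0.37 in morphants and 13.19 ± 1.22 in wild type and did not pass (adjusted p = 0.0839). Among title numbers up to 12 the leukocyte difference was 0.22 (exact permutation p = 0.121, 5 morphant and 7 wild-type arrays). Above 12 it was 0.77 (exact permutation p = 0.00303, 4 and 7 arrays), and with these number groups as a block 0.48. Morphant scores were alike in both number groups, while wild-type scores ran from 8.14 to 8.71 up to number 12 and from 7.67 to 8.27 above it. Among other rises were ckmt2a (listed as zgc:56085, 2.44 ± 0.65), a creatine kinase of muscle mitochondria, the homeobox gene hoxa10b (2.25 ± 0.56) and olig4 (2.15 ± 0.50). Heme oxygenase hmox1a (listed as hmox1) rose by 1.97 ± 0.40 and gadd45aa, a stress-response gene, by 1.75 ± 0.39.

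For the cell cycle list, of 25 measured members 6 rose, 1 fell and 18 did not pass. With p adjusted over the list alone, 10 rose and 4 fell. With the near-duplicate pairs averaged, 3 rose and 0 fell. The score of the list differed by 0.32 (adjusted p = 0.153, higher than the wild-type median in 8 of 9 arrays). Camera called it as higher at the preset correlation (adjusted p = 0.015), but not with an estimated one (adjusted p = 0.637). The mitotic genes top2a (1.33 ± 0.31), kif11 (1.38 ± 0.35) and aurka (1.56 ± 0.40) rose, the replication helicase subunit mcm7 fell (-1.21 ± 0.31), and the spindle protein nusap1, outside the list, rose by 2.13 ± 0.42. For the testicular somatic list, of 19 measured members 0 rose, 2 fell and 17 did not pass. Of all 19 members, 1 rose and 3 fell when adjusted over the list alone. The testicular score differed by -0.11 (adjusted p = 0.201, lower than the wild-type median in 7 of 9 arrays). The androgen receptor ar fell, with 10.75 ± 0.39 in morphants and 11.60 ± 0.43 in wild type (-0.86 ± 0.18, adjusted p = 0.00568, 9 of 9 arrays). So did the sex-determination factor dmrt1, with 5.61 ± 0.30 in morphants and 6.24 ± 0.36 in wild type (-0.63 ± 0.16, adjusted p = 0.0255, 9 of 9 arrays). The growth factor gsdf (-1.10 ± 0.36, adjusted p = 0.0838), amh (0.03 ± 0.30, adjusted p = 0.972) and sox9a (-0.56 ± 0.28) did not pass. For the ovarian somatic list, of 19 measured members 1 rose, 0 fell and 18 did not pass. When adjusted over the list alone, 1 rose and 0 fell. The ovarian score differed by -0.02 (adjusted p = 0.854, lower than the wild-type median in 3 of 9 arrays), and its sign changed without morphant array 14 (0.0121), wild-type array 19 (0.0169) or wild-type array 20 (0.0051). The member that rose was wnt4 (listed as wnt4a, 0.95 ± 0.27). Aromatase, cyp19a1a, differed by 0.10 ± 0.41 (adjusted p = 0.936), and foxl2a (listed as foxl2) stood at 5.36 ± 1.07 in morphants and 6.09 ± 1.01 in wild type (adjusted p = 0.363). For the cholesterol synthesis list, of 20 measured members 0 rose, 1 fell and 19 did not pass. Counts adjusted over the list alone were 0 rising and 1 falling. The fall was idi1 (-0.70 ± 0.16), and the score differed by -0.30 (adjusted p = 0.531, lower than the wild-type median in 6 of 9 arrays).

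The pathway lists that remained did not pass at 14 dpf by the exact permutation test of their scores. The Wnt pathway list differed by 0.18 (adjusted p = 0.0837, higher than the wild-type median in 8 of 9 arrays). For Wnt pathway, 2 and 0 of 31 members rose and fell (2 and 0 adjusted over the list alone, 0 and 0 with the near-duplicate pairs averaged). The TGF-beta and BMP pathway list differed by 0.15 (adjusted p = 0.153, higher than the wild-type median in 7 of 9 arrays). For TGF-beta and BMP pathway, 1 and 0 of 36 members rose and fell (3 and 0 adjusted over the list alone, 0 and 0 with the near-duplicate pairs averaged). The p53 response and apoptosis list differed by 0.16 (adjusted p = 0.305, higher than the wild-type median in 6 of 9 arrays). For p53 response and apoptosis, 1 and 0 of 23 members rose and fell (2 and 0 adjusted over the list alone). The NF-kB and inflammation list differed by 0.36 (adjusted p = 0.153, higher than the wild-type median in 6 of 9 arrays). For NF-kB and inflammation, 1 and 0 of 21 members rose and fell (1 and 0 adjusted over the list alone). The immediate early and stress list differed by 0.08 (adjusted p = 0.771, higher than the wild-type median in 6 of 9 arrays). For immediate early and stress, 1 and 0 of 22 members rose and fell (1 and 1 adjusted over the list alone). The circadian clock list differed by -0.13 (adjusted p = 0.281, lower than the wild-type median in 6 of 9 arrays). For circadian clock, 1 and 0 of 29 members rose and fell (2 and 4 adjusted over the list alone, 0 and 1 with the near-duplicate pairs averaged). For the rest no member changed, also when adjusted over the list alone. Their score differences were steroidogenesis 0.10 (adjusted p = 0.556, higher than the wild-type median in 5 of 9 arrays) and spermatid and flagellum 0.11 (adjusted p = 0.452, higher than the wild-type median in 4 of 9 arrays). Further ones were retinoid pathway 0.00 (adjusted p = 0.957, higher than the wild-type median in 5 of 9 arrays) and estrogen-responsive liver -0.17 (adjusted p = 0.153, lower than the wild-type median in 7 of 9 arrays). The median member and the score had opposite signs for the retinoid list (-0.01 and 0.00), and leaving out any of 8 arrays changed the sign of that score (-0.0343 to -0.0029). Camera at the preset correlation called NF-kB and inflammation as higher (adjusted p = 0.00755), and with an estimated one it did not (adjusted p = 0.285).

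Markers of the other tissues of a trunk did not pass as lists at 14 dpf either, by the same exact permutation test. The kidney list differed by -0.05 (adjusted p = 0.578, lower than the wild-type median in 9 of 9 arrays). For kidney, 1 and 1 of 20 members rose and fell (1 and 1 adjusted over the list alone, 0 and 1 with the near-duplicate pairs averaged). The epidermis list differed by -0.24 (adjusted p = 0.201, lower than the wild-type median in 4 of 9 arrays). For epidermis, 0 and 2 of 19 members rose and fell (0 and 4 adjusted over the list alone, 0 and 0 with the near-duplicate pairs averaged). The bone and cartilage list differed by 0.06 (adjusted p = 0.776, higher than the wild-type median in 6 of 9 arrays). For bone and cartilage, 0 and 0 of 19 members rose and fell (1 and 0 adjusted over the list alone). The blood list differed by 0.47 (adjusted p = 0.153, higher than the wild-type median in 7 of 9 arrays). For blood, 1 and 0 of 19 members rose and fell (1 and 0 adjusted over the list alone, 0 and 0 with the near-duplicate pairs averaged). For the rest no member changed, also when adjusted over the list alone. Their score differences were skeletal muscle 0.06 (exact permutation p = 0.333 before adjustment, higher than the wild-type median in 5 of 9 arrays) and exocrine pancreas 0.84 (adjusted p = 0.281, higher than the wild-type median in 7 of 9 arrays). Further ones were liver -0.39 (adjusted p = 0.854, lower than the wild-type median in 4 of 9 arrays) and intestine -0.24 (adjusted p = 0.268, lower than the wild-type median in 7 of 9 arrays). Then came nervous tissue 0.15 (exact permutation p = 0.32 before adjustment, higher than the wild-type median in 6 of 9 arrays) and adipose and lipid storage -0.18 (adjusted p = 0.268, lower than the wild-type median in 7 of 9 arrays). For bone and cartilage the median member (-0.04) and the score had opposite signs. Wild-type array 10 stood at 12.6 for the liver list, and without it the difference was 0.07. Without the same array the intestine difference was -0.16 and the adipose difference -0.12. At this age leaving out an array moved the difference more than 1.5 times for 17 of the 24 lists that did not pass. At the preset correlation camera called blood as higher (adjusted p = 0.000242), epidermis as lower (adjusted p = 0.00141) and exocrine pancreas as higher (adjusted p = 0.0077). With an estimated correlation none of these passed (adjusted p = 0.362, 0.362 and 0.67).

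In all, limma called 780 of the 31475 rows at 14 dpf, 362 higher and 418 lower in morphants. Of these, 452 had a gene name. Centring arrays on their median gave 493 higher and 328 lower. A fit of only the groups compared, which takes the spread from this age alone, gave 195 calls. The arrays hold 6 pairs of near-duplicates. With these averaged to 41 samples there were 400 calls, 149 higher and 251 lower, 396 of them among the 780. The germ plasm and leukocyte lists then had adjusted p values of 0.000394 and 0.0105. Of the genes named as changed, avd, ckmt2a, hoxa10b, spi1b, mcm7, dmrt1 and wnt4 then had adjusted p values from 0.0513 to 0.0943, and nanos3 one of 0.0487. Lower title numbers alone gave 45 calls (5 morphant and 7 wild-type arrays) and higher ones 897 (4 and 7 arrays).

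**Figure D1:**
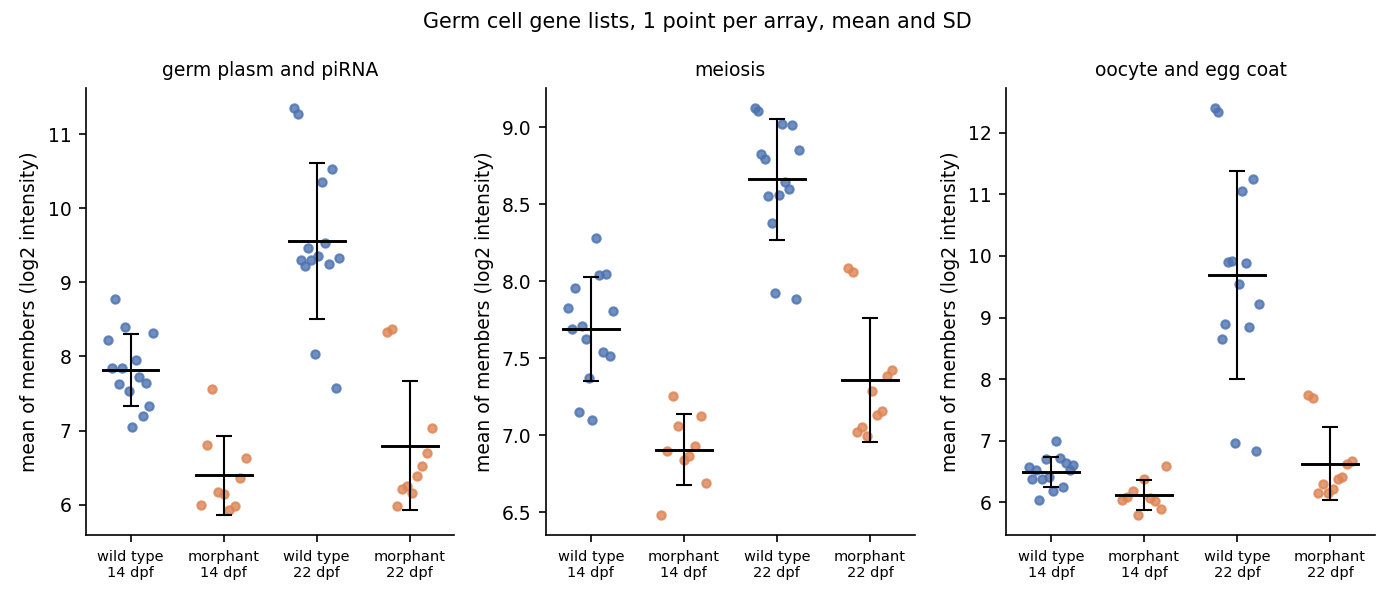
Scores of the germ plasm and piRNA, meiosis, and oocyte and egg coat lists (mean log2 intensity of the members, vertical axes) in each group, with 1 point per array and bars for the mean and SD. Morphant arrays lie below the wild-type mean of their age for germ plasm and piRNA at both ages, and the wild-type oocyte scores at 22 dpf are the most spread, with an SD of 1.69.

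The comparison at 22 dpf put the same question to older fish. Transcripts of oocytes, of meiosis and of germ plasm were far lower in morphants than in wild type, and so were several genes of the ovarian soma. The oocyte and egg coat list averaged 6.63 ± 0.60 (SD, n = 10) in morphants and 9.69 ± 1.69 (SD, n = 14) in wild type. By a permutation test the difference was -3.06 (adjusted p = 0.00035), and 10 of 10 morphant arrays lay below the wild-type median. The germ plasm and piRNA list averaged 6.79 ± 0.87 (SD, n = 10) in morphants and 9.56 ± 1.05 (SD, n = 14) in wild type. It differed by -2.77 (adjusted p = 0.00028, permutation test), and 10 of 10 morphant arrays lay below the wild-type median. The meiosis list averaged 7.36 ± 0.40 (SD, n = 10) in morphants and 8.66 ± 0.39 (SD, n = 14) in wild type, with a difference of -1.30 (adjusted p = 0.00028, permutation test), and 10 of 10 morphant arrays lay below the wild-type median. Lists of exocrine pancreas and of adipose tissue were higher in morphants, though that of pancreas lost its call with near-duplicate arrays averaged and in camera with an estimated correlation.

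For the oocyte and egg coat list, of 26 measured members 0 rose, 24 fell and 2 did not pass. With p adjusted over the list alone, 0 rose and 25 fell. The oogenesis-related gene org averaged 6.36 ± 1.81 in morphants and 11.52 ± 1.41 in wild type (-5.17 ± 0.57, adjusted p = 4.19e-08, 10 of 10 arrays). The egg coat genes zp2.2 (-5.24 ± 0.75, adjusted p = 3.26e-06, 10 of 10 arrays), zp2.5 (-5.14 ± 0.72) and zp3 (-4.54 ± 0.66) fell, and so did the poly(A)-binding pabpc1l (-4.27 ± 0.57), the oocyte kinase wee2 (-3.96 ± 0.56) and zar1, a maternal-effect gene (-3.70 ± 0.51). The oocyte transcription factor figla averaged 5.56 ± 1.21 in morphants and 8.47 ± 1.72 in wild type (-2.91 ± 0.55, 10 of 10 arrays), and the oocyte growth factors bmp15 (-2.36 ± 0.44) and gdf9 (-1.17 ± 0.35, adjusted p = 0.0456) fell as well. The largest fall outside the lists was that of the claudin cldnd (-5.72 ± 0.90, adjusted p = 1.53e-05, 10 of 10 arrays). Others outside the lists were the amino acid transporter slc7a1b (listed as zgc:63694, -5.24 ± 0.85), zpax4 (listed as wu:fi38e01, -5.03 ± 0.80), of the egg coat gene family, avd (-5.22 ± 0.66), tmsb5 (listed as si:dkey-167i21.2, -5.09 ± 0.66) and the nucleoplasmin npm2b (listed as npm2, -5.01 ± 0.67).

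For the germ plasm and piRNA list, of 20 measured members 0 rose, 18 fell and 2 did not pass. Of all 20 members, 0 rose and 19 fell when adjusted over the list alone. Ddx4 averaged 7.35 ± 1.93 in morphants and 11.54 ± 0.90 in wild type (-4.19 ± 0.56, adjusted p = 9.1e-07, 10 of 10 arrays). Buc, the organizer of the Balbiani body of oocytes, averaged 6.78 ± 2.02 in morphants and 11.67 ± 1.96 in wild type (-4.90 ± 0.68, adjusted p = 1.68e-06, 10 of 10 arrays). The Tudor-domain gene rnf17 (-3.18 ± 0.40), the Piwi proteins piwil2 (-2.76 ± 0.35) and piwil1 (-2.66 ± 0.35), dazl (-2.08 ± 0.30) and nanos3 (-1.04 ± 0.29, adjusted p = 0.0305) fell as well. For the meiosis list, of 24 measured members 0 rose, 13 fell and 11 did not pass. When adjusted over the list alone, 0 rose and 14 fell. Smc1b changed by -4.60 ± 0.55, hormad1 by -3.46 ± 0.45, spo11, which makes the breaks that start meiotic recombination, by -3.13 ± 0.37, stag3 by -2.66 ± 0.31 and sycp3 by -2.36 ± 0.46, each in 10 of 10 arrays. Each of the germ plasm, meiosis and oocyte lists kept its call in camera with an estimated correlation. With scores of 4 other tissues as covariates the differences were smaller, at -1.65 for the oocyte list, -1.80 for germ plasm and -0.96 for meiosis, and all passed (adjusted p = 0.00266, 0.00042 and 0.00042). Among title numbers up to 12 the oocyte list differed by -2.86 (exact permutation p = 0.0222, 4 morphant and 8 wild-type arrays). Above 12 it differed by -3.11 (exact permutation p = 0.00216, 6 and 6 arrays). The germ plasm list differed by -2.44 and -2.92. The 4 morphant arrays of the lower numbers are both near-duplicate pairs of that group. Among the wild-type arrays of the lower numbers, 5 and 6, 7 and 8, and 9 and 10 are pairs too. Exact permutation p values of the lower numbers at this age may therefore be too small.

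The ovarian somatic list averaged 6.93 ± 0.21 (SD, n = 10) in morphants and 7.46 ± 0.20 (SD, n = 14) in wild type. The ovarian difference was -0.53 (adjusted p = 0.00028, permutation test), and 10 of 10 morphant arrays lay below the wild-type median. It held its call in camera with an estimated correlation. For this list, of 19 measured members 0 rose, 5 fell and 14 did not pass. Counts adjusted over the list alone were 0 rising and 5 falling. Aromatase, cyp19a1a, which makes estrogen, fell, with 4.94 ± 1.03 in morphants and 7.30 ± 1.13 in wild type (-2.37 ± 0.40, adjusted p = 4.7e-05, 10 of 10 arrays). The ovarian transcription factors foxl2a (-2.24 ± 0.39, adjusted p = 7.94e-05, 10 of 10 arrays) and foxl2b (listed as loc100149117, -2.15 ± 0.37, adjusted p = 6.58e-05, 10 of 10 arrays) fell too. So did the steroid enzyme hsd17b1 (-1.38 ± 0.26, adjusted p = 0.000336, 10 of 10 arrays). For the steroidogenesis list, of 15 measured members 0 rose, 2 fell and 13 did not pass. With p adjusted over the list alone, 0 rose and 2 fell. The falls were cyp19a1a and hsd17b1, which the ovarian somatic list holds too. Its score differed by -0.43 (adjusted p = 0.00172, lower than the wild-type median in 10 of 10 arrays) and had an adjusted p = 0.112 with an estimated correlation. For the estrogen-responsive liver list, of 11 measured members 0 rose, 1 fell and 10 did not pass. Of all 11 members, 1 rose and 5 fell when adjusted over the list alone. The estrogen-responsive score averaged 5.66 ± 0.14 (SD, n = 10) in morphants and 5.99 ± 0.21 (SD, n = 14) in wild type. This lies near the lower end of the scale, which limits what the list can show. The estrogen-responsive score differed by -0.33 (adjusted p = 0.00145, lower than the wild-type median in 10 of 10 arrays). The fall was that of the yolk precursor vtg4, at the low level of 4.86 ± 0.27 in morphants and 5.54 ± 0.55 in wild type (-0.68 ± 0.18). In lower and higher title numbers the ovarian somatic difference was -0.59 (exact permutation p = 0.00202) and -0.42 (exact permutation p = 0.013). The steroidogenesis difference was -0.35 (exact permutation p = 0.0364) and -0.40 (exact permutation p = 0.013). The estrogen-responsive one was -0.22 (exact permutation p = 0.0667) and -0.44 (exact permutation p = 0.00433). The lower numbers hold near-duplicate pairs in both genotypes, so their p values may be too small. When only rows above the median row were kept, the ovarian somatic score differed by 0.03 (adjusted p = 0.795), a step that removes cyp19a1a, foxl2a, foxl2b and hsd17b1. With tissue scores as covariates it differed by -0.33 (adjusted p = 0.000467), and the steroidogenesis score by -0.20 (adjusted p = 0.0972).

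For the testicular somatic list, of 19 measured members 0 rose, 3 fell and 16 did not pass. When adjusted over the list alone, 0 rose and 3 fell. Its score differed by -0.10 (adjusted p = 0.311, lower than the wild-type median in 8 of 10 arrays). The falls were gsdf, 5.96 ± 0.75 in morphants and 7.52 ± 0.59 in wild type (-1.55 ± 0.35, adjusted p = 0.00284, 10 of 10 arrays), dmrt1 (-0.56 ± 0.16, adjusted p = 0.0297, 10 of 10 arrays) and the gonadal growth factor igf3 (-1.24 ± 0.35, adjusted p = 0.0297, 10 of 10 arrays). Amh, the anti-Müllerian hormone, stood at 5.68 ± 0.72 in morphants and 5.40 ± 0.71 in wild type (0.28 ± 0.29, adjusted p = 0.766). Sox9a, a factor of Sertoli cells, stood at 5.35 ± 0.84 in morphants and 5.03 ± 0.40 in wild type (0.32 ± 0.27, adjusted p = 0.679). Neither passed. For the spermatid and flagellum list, of 21 measured members 0 rose, 2 fell and 19 did not pass. Counts adjusted over the list alone were 0 rising and 3 falling. Among the falls was spata4 (-1.31 ± 0.33), and the score differed by -0.04 (adjusted p = 0.77, lower than the wild-type median in 6 of 10 arrays). For the retinoid pathway list, of 27 measured members 0 rose, 2 fell and 25 did not pass. With p adjusted over the list alone, 3 rose and 3 fell. The retinoid score differed by -0.08 (adjusted p = 0.374, lower than the wild-type median in 7 of 10 arrays). Among its falls was stra6 (-2.81 ± 0.51, adjusted p = 0.000173, 10 of 10 arrays).

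The exocrine pancreas list averaged 11.47 ± 1.78 (SD, n = 10) in morphants and 9.34 ± 1.54 (SD, n = 14) in wild type. The pancreas difference was 2.13 (adjusted p = 0.0231, permutation test), and 8 of 10 morphant arrays lay above the wild-type median. With the near-duplicate pairs averaged its difference was 1.80 (adjusted p = 0.167). In camera it had an adjusted p = 0.112 with an estimated correlation. For this list, of 17 measured members 6 rose, 0 fell and 11 did not pass. Of all 17 members, 16 rose and 0 fell when adjusted over the list alone. Most of the largest rises at 22 dpf were genes of digestive enzymes. The amylase amy2al2 (listed as zgc:92137) averaged 10.91 ± 3.60 in morphants and 6.94 ± 2.79 in wild type (3.98 ± 1.09, adjusted p = 0.0257, 8 of 10 arrays). Others that rose were the chymotrypsinogen ctrb.3 (listed as zgc:112160, 3.88 ± 1.14), the elastases cela1.3 (listed as zgc:92745, 3.44 ± 0.89), cela1.2 (listed as loc100535584, 2.85 ± 0.71) and cela1.4 (listed as zgc:112302, 2.87 ± 0.78). Rises were also found for carboxypeptidase cpb1 (3.07 ± 0.84), the lipase cel.2 (listed as cell, 2.77 ± 0.70) and the astacin proteases c6ast4 (3.21 ± 0.88) and c6ast3 (2.84 ± 0.81). Selenoe (listed as fep15) rose by 3.65 ± 0.94. None of these enzyme genes passed with the pairs averaged, where their adjusted p values ran from 0.15 to 0.277. The pancreas list differed by 3.36 (exact permutation p = 0.00202, 4 morphant and 8 wild-type arrays) among title numbers up to 12. Above 12 it differed by 0.88 (exact permutation p = 0.485, 6 and 6 arrays), and with these number groups as a block by 2.04. The arrays up to 12 hold near-duplicate pairs in both genotypes, so the p value of the lower numbers may be too small.

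The adipose and lipid storage list averaged 7.16 ± 0.25 (SD, n = 10) in morphants and 6.71 ± 0.20 (SD, n = 14) in wild type. The adipose difference was 0.44 (adjusted p = 0.000672, permutation test), and 10 of 10 morphant arrays lay above the wild-type median. It kept its call in camera with an estimated correlation, and with tissue scores as covariates the difference was 0.29 (adjusted p = 0.00324). For this list, of 15 measured members 4 rose, 0 fell and 11 did not pass. When adjusted over the list alone, 6 rose and 0 fell. Fabp4a (listed as fabp11a), a fatty acid carrier of adipocytes, rose, with 12.65 ± 0.33 in morphants and 11.87 ± 0.54 in wild type (0.78 ± 0.18, adjusted p = 0.00558, 9 of 10 arrays). The other rises were cidec (listed as si:dkey-91f15.6, 1.48 ± 0.39, adjusted p = 0.0178, 10 of 10 arrays), a protein of lipid droplets, dgat2 (1.39 ± 0.35, adjusted p = 0.0119, 9 of 10 arrays), which makes triglycerides, and the desaturase scd (0.91 ± 0.27, adjusted p = 0.0409, 9 of 10 arrays). In lower and higher title numbers the list differed by 0.62 (exact permutation p = 0.00202) and by 0.32 (exact permutation p = 0.0801). The first of these p values may be too small, as the lower numbers hold near-duplicate pairs in both genotypes. The immune gene irg1l rose at 22 dpf as at 14 dpf, with 9.01 ± 2.02 in morphants and 6.09 ± 0.57 in wild type (2.92 ± 0.64, adjusted p = 0.00227, 10 of 10 arrays). The leukocyte list differed by 0.10 (adjusted p = 0.532, higher than the wild-type median in 8 of 10 arrays), with no member changed, also when adjusted over the list alone.

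The lists that remained, of pathways and of other tissues, did not pass at 22 dpf by the permutation test of their scores. The nervous tissue list differed by 0.22 (adjusted p = 0.311, higher than the wild-type median in 8 of 10 arrays). For nervous tissue, 0 and 0 of 23 members rose and fell (2 and 0 adjusted over the list alone). For the rest no member changed, also when adjusted over the list alone. Their score differences were Wnt pathway 0.07 (adjusted p = 0.374, higher than the wild-type median in 9 of 10 arrays) and TGF-beta and BMP pathway 0.07 (adjusted p = 0.443, higher than the wild-type median in 5 of 10 arrays). Further ones were p53 response and apoptosis 0.09 (adjusted p = 0.388, higher than the wild-type median in 6 of 10 arrays) and NF-kB and inflammation 0.11 (adjusted p = 0.374, higher than the wild-type median in 9 of 10 arrays). Then came cell cycle -0.19 (adjusted p = 0.388, lower than the wild-type median in 7 of 10 arrays) and cholesterol synthesis 0.11 (adjusted p = 0.546, higher than the wild-type median in 6 of 10 arrays). Others were immediate early and stress -0.01 (adjusted p = 0.955, lower than the wild-type median in 6 of 10 arrays) and circadian clock 0.09 (adjusted p = 0.546, higher than the wild-type median in 5 of 10 arrays). More were skeletal muscle 0.08 (adjusted p = 0.139, higher than the wild-type median in 10 of 10 arrays) and liver -0.11 (adjusted p = 0.861, lower than the wild-type median in 9 of 10 arrays). Further ones were intestine 0.13 (adjusted p = 0.311, higher than the wild-type median in 8 of 10 arrays) and kidney 0.14 (adjusted p = 0.311, higher than the wild-type median in 8 of 10 arrays). Then came epidermis 0.07 (adjusted p = 0.575, higher than the wild-type median in 6 of 10 arrays) and bone and cartilage 0.18 (adjusted p = 0.311, higher than the wild-type median in 6 of 10 arrays). Others were blood 0.06 (adjusted p = 0.77, higher than the wild-type median in 4 of 10 arrays). The median member and the score had opposite signs for the spermatid (0.03), retinoid (0.08), liver (0.01) and immediate early (0.06) lists, whose median members are given here. Without morphant array 14, at 11.6, the liver difference was -0.63, and without wild-type array 22, at 10.5, it was 0.16. Leaving out an array moved the difference more than 1.5 times for 11 of the 20 lists that did not pass at this age. The sign changed for blood without morphant array 13 (-4e-04), and for immediate early and stress without any of 9 arrays (0.00 to 0.07). Camera at the preset correlation called nervous tissue as higher (adjusted p = 0.00483), and with an estimated one it did not (adjusted p = 0.497).

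In all, limma called 1097 rows at 22 dpf, 186 higher and 911 lower in morphants, of which 451 had a gene name. With the near-duplicate pairs averaged there were 667 calls, 36 higher and 631 lower, 666 of them among the 1097. The oocyte, germ plasm and ovarian somatic lists then had adjusted p values of 0.00241, 0.000741 and 0.00185. The members called as falling in these lists then numbered 20, 18 and 4, with 11 for meiosis, and 1 member of the adipose list was called as rising. Beyond the pancreas genes, gdf9, dmrt1, igf3, spata4, vtg4, dgat2, cidec and scd then had adjusted p values from 0.0706 to 0.181.

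**Figure D2:**
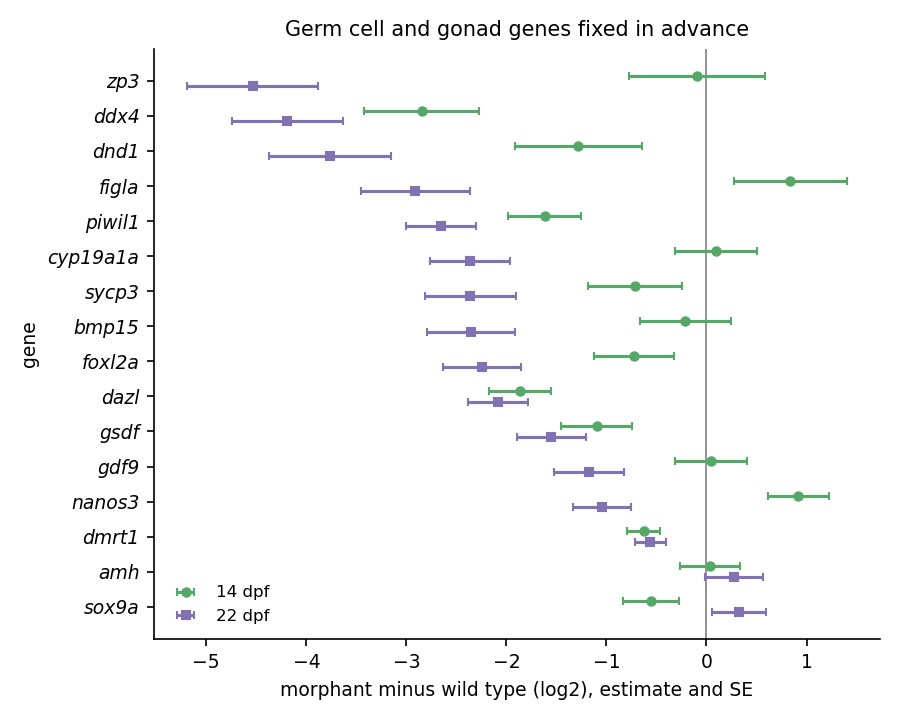
Morphant minus wild-type difference (log2, horizontal axis) of 16 germ cell and gonad genes named in advance (vertical axis), with circles for 14 dpf, squares for 22 dpf and bars for the SE. At 22 dpf every gene of the 16 except amh and sox9a lies below 0, and at 14 dpf nanos3 (0.92) and figla (0.84) lie farthest above it.

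**Figure D3:**
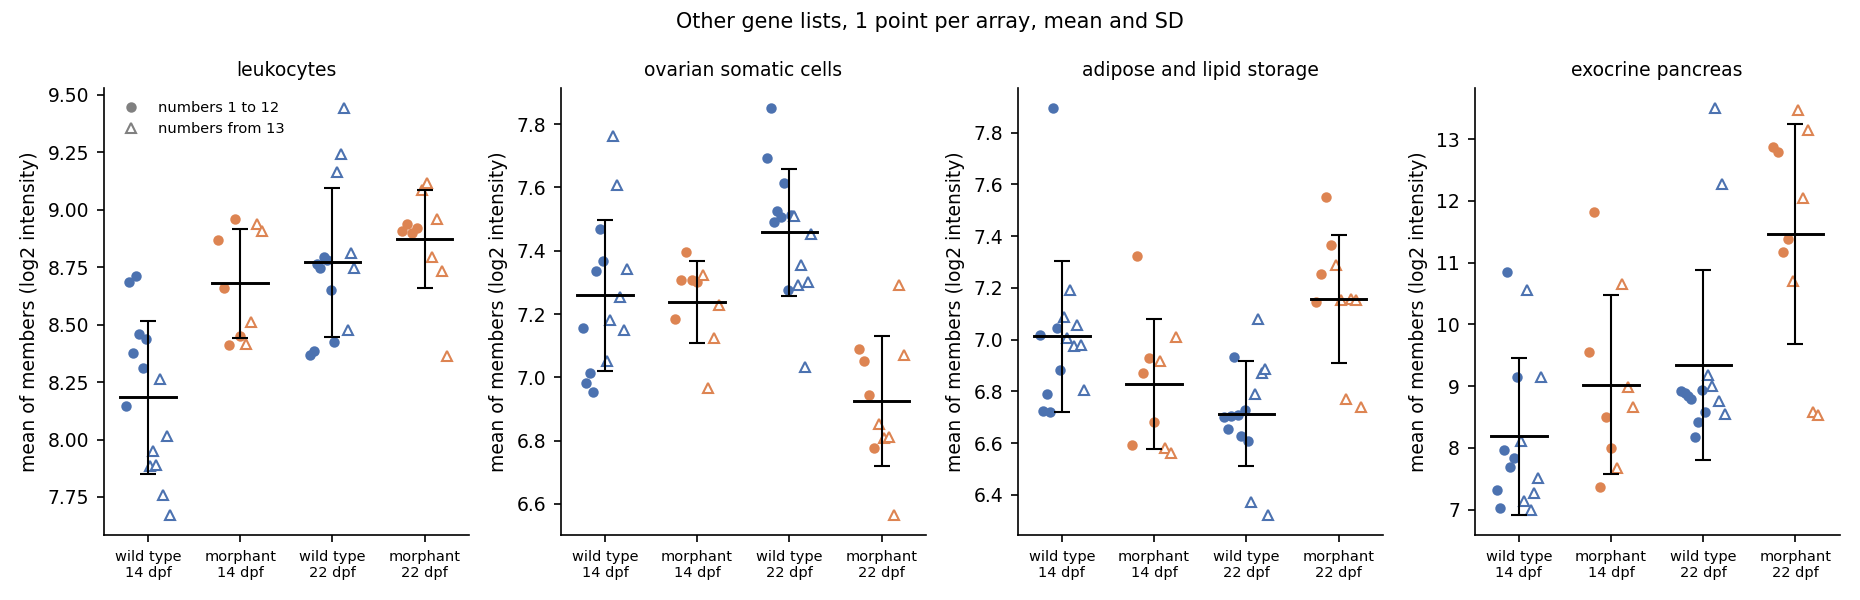
Scores of the leukocyte, ovarian somatic, adipose and exocrine pancreas lists (mean log2 intensity of the members, vertical axes) in each group, with filled circles for title numbers 1 to 12, open triangles for later numbers, and bars for the mean and SD. The leukocyte score is higher in morphants at 14 dpf (8.68 against 8.18), and the pancreas score at 22 dpf is the most spread, with an SD of 1.78 in morphants.

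The difference of the morphant effect between the ages asked where germ cell loss went with a larger change at one age than at the other. Of the lists, that of oocyte and egg coat had the largest value. The oocyte and egg coat list fell by 0.37 at 14 dpf and by 3.06 at 22 dpf, and by limma on the scores the effects differed by -2.69 ± 0.57 (adjusted p = 0.000677). Here 8 of 9 and 10 of 10 morphant arrays lay below the wild-type median. At 14 dpf the oocyte score stood at 6.49 even in wild type, near the lower end of the scale, where a large fall can hardly show. The smaller effect at 14 dpf may come from this, and the ages were taken as normalized in separate runs. Lower effects at 22 dpf were also found for the germ plasm and piRNA list (-1.35 ± 0.46, adjusted p = 0.0291), the ovarian somatic list (-0.51 ± 0.12, adjusted p = 0.00128) and the steroidogenesis list (-0.53 ± 0.17, adjusted p = 0.0195). The adipose and lipid storage list (0.63 ± 0.15, adjusted p = 0.00128) had a higher one. The germ plasm call was lost without morphant array 3 of 14 dpf (difference -1.20, adjusted p = 0.0679). It was lost too without morphant array 3 (-1.26, adjusted p = 0.0542) or 14 (-1.28, adjusted p = 0.0501) of 22 dpf. It was also lost without low rows (difference -1.59, adjusted p = 0.0504) and with tissue covariates (adjusted p = 0.118). The ovarian call was lost without low rows (adjusted p = 0.299) and the steroidogenesis call with z-scores (adjusted p = 0.0775). The meiosis list, -0.52 ± 0.21 (adjusted p = 0.0765), and the testicular somatic list, 0.01 ± 0.09 (adjusted p = 0.922), did not pass. Neither did the leukocyte list, -0.40 ± 0.17 (adjusted p = 0.0996), the cell cycle list, -0.52 ± 0.23 (adjusted p = 0.0996), and the exocrine pancreas list, 1.29 ± 0.87 (adjusted p = 0.298).

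Limma called 203 rows for this difference, 29 higher and 174 lower, of which 81 had a gene name. The largest negative values were those of cldnd (-6.17, adjusted p = 0.0132), zpax4 (-5.67 ± 1.15), slc7a1b (-5.12 ± 1.22), zpax1 (listed as si:dkeyp-50f7.2, -4.70 ± 0.98), zp3 (-4.44 ± 0.94), zp2.2 (-4.32 ± 1.08) and larp6b (listed as zgc:162969, -4.23 ± 0.76, adjusted p = 0.00704), with 10 of 10 morphant arrays below the wild-type median at 22 dpf for each. Of the oocyte list, pabpc1l (-3.98 ± 0.82), figla (-3.75 ± 0.78), zar1 (-3.55 ± 0.74) and lhx8a (-2.48 ± 0.46), a transcription factor of young oocytes, passed. Cyp19a1a had no difference past the threshold at 14 dpf and fell at 22 dpf, and the effects differed by -2.46 ± 0.57, adjusted p = 0.0282. Zp3 and cyp19a1a stood near the lower end of the scale in wild type at 14 dpf, which limits a fall at that age. Nanos3 stood higher in morphants at 14 dpf without passing and fell at 22 dpf, and the effects differed by -1.96 ± 0.42, adjusted p = 0.0153. The mitotic genes aurka (-2.53 ± 0.55) and birc5a (-1.34 ± 0.31) and hmox1a (-2.27 ± 0.56) had lower effects at 22 dpf, while the cell cycle list as a whole did not pass. Positive values included ugt5a4 (2.55 ± 0.60), a glucuronosyltransferase, nceh1a (2.04 ± 0.51), a cholesterol ester hydrolase, the myosin chaperone unc45b (1.79 ± 0.39) and the filamin flnca (1.62 ± 0.37). With the near-duplicate pairs averaged 66 rows passed, all among the 203. Slc7a1b, zp2.2, figla, cyp19a1a, aurka, birc5a, hmox1a, ugt5a4, flnca and nceh1a no longer did (adjusted p from 0.0523 to 0.16).

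The overlap of the calls at the 2 ages asked which transcripts changed at both, where the ages share no array. There were 106 rows called in both comparisons in one direction, 92 of them lower and 14 higher, against 12.1 and 2.14 by chance, and 0 were called in opposite directions. The shared falls included smc1b, hormad1, stag3, ddx4, piwil1, dazl, org, avd and dmrt1, and the shared rises included irg1l. Across genes the effects at the 2 ages correlated with r = 0.289, where genes are not independent replicates. With the pairs averaged 75 rows were shared, 73 lower and 2 higher, and 1 was called in opposite directions. Avd and dmrt1 then did not pass at 14 dpf. With tissue scores as covariates 50 rows were shared, 50 lower and 0 higher.

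The levels at the 2 ages describe each group during development. The oocyte and egg coat score stood at 6.49 ± 0.25 (SD, n = 14) at 14 dpf and 9.69 ± 1.69 (SD, n = 14) at 22 dpf in wild type, and at 6.12 ± 0.24 (SD, n = 9) and 6.63 ± 0.60 (SD, n = 10) in morphants. For the egg coat gene zp3 the wild-type levels were 5.75 and 10.86 and the morphant levels 5.65 and 6.32. Cyp19a1a stood at 5.28 and 7.30 in wild type and at 5.38 and 4.94 in morphants. These differences between ages were not tested, since arrays of different age shared almost no exact value in the low tail, as arrays normalized in separate runs do.

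The spread of the germ cell lists between wild-type arrays was compared between the ages, since fish of 22 dpf can be at different stages of gonad differentiation. The mean absolute deviation of the oocyte and egg coat score from its group median was 1.27 in wild type at 22 dpf and 0.19 at 14 dpf, a difference of 1.08 (permutation p = 0.00015, adjusted p = 0.00075 over 5 lists), and 1.07 with the pairs averaged (adjusted p = 0.00105). At 14 dpf this score lay near the lower end of the scale, where a spread can be compressed, and the ages were taken as normalized in separate runs, which the test does not separate from a difference between fish. The germ plasm and piRNA (0.33, adjusted p = 0.398), meiosis (0.04, adjusted p = 0.84), ovarian somatic (-0.05, adjusted p = 0.677) and testicular somatic (0.00, adjusted p = 0.909) lists did not pass. Morphants at 22 dpf had a deviation of 0.39 for the oocyte score, a difference of -0.88 from wild type, which did not pass after correction (permutation p = 0.0234, adjusted p = 0.117). For the other lists the deviation in morphants less that in wild type was -0.11 (germ plasm and piRNA, adjusted p = 0.915), -0.01 (meiosis, adjusted p = 0.929), 0.02 (ovarian somatic, adjusted p = 0.915) and -0.03 (testicular somatic, adjusted p = 0.915).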

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

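The counts over other splits of the arrays were set before the results were seen, whereas the rotations below and the tests of the leukocyte, exocrine pancreas and near-duplicate patterns were chosen after. Of 100 splits of the arrays within each age, the real one included, 1 gave as many calls as the real split in each comparison. This would argue against chance as the whole account only if all arrays varied independently, and those of the near-duplicate pairs did not. The real counts were 780 at 14 dpf against a highest other of 56, 1097 at 22 dpf against 6, 203 for the difference of effects against 4, and 106 shared calls against 0. These splits break up near-duplicate pairs and runs of title numbers, so the labels were also rotated along the numbers, which keeps such runs together. Of 132 rotations at 14 dpf and 144 at 22 dpf, 1 each, the real one, gave as many calls. The others gave a median of 1 and 0 calls. Their highest were 435, with 21 of 23 labels as in the real one, and 758, with 4 of 24, which is close to the real labels exchanged. The difference of effects and the shared calls were not rotated. Morphants hold the lowest numbers of each number group, so an effect of number order within a group was not separated from genotype.

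Differences of the morphant effect between the ages, each past its test, form the largest group. The effect at 22 dpf less that at 14 dpf was -2.69 for the oocyte and egg coat list, -1.35 for germ plasm and piRNA, -0.53 for steroidogenesis, -0.51 for ovarian somatic cells and 0.63 for adipose and lipid storage. For the oocyte list the low wild-type level at 14 dpf limits a fall at that age. Among oocyte and egg coat genes and others that fell at 22 dpf it was -6.17 for cldnd, -5.67 for zpax4, -5.12 for slc7a1b, -4.70 for zpax1, -4.44 for zp3, -4.32 for zp2.2, -4.23 for larp6b, -3.98 for pabpc1l, -3.75 for figla, -3.55 for zar1 and -2.48 for lhx8a. It was -2.46 for cyp19a1a, -1.96 for nanos3, -2.53 for aurka, -1.34 for birc5a and -2.27 for hmox1a. Positive differences were 2.55 for ugt5a4, 2.04 for nceh1a, 1.79 for unc45b and 1.62 for flnca.

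Single arrays stood apart from their group in 12 of 167 values of morphant groups checked, where the threshold of the rule has a nominal rate of about 1 in 20. The rate that chance gives for these values was not tested. The larger wild-type groups were not checked for this. The gap to the nearest array is given as a share of the range of the group. Morphant array 3 at 14 dpf was the highest of its group for ddx4 (0.6, at 10.9), piwil1 (0.607), dazl (0.597), hormad1 (0.567), smc1b (0.507) and foxl2a (0.547). At the same age array 2 was high for cyp19a1a (0.744) and array 15 low for mhc1zaa (0.692). At 22 dpf morphant array 14 was high for the liver list (0.904, at 11.6 against 6.68) and the intestine list (0.531), array 18 low for the leukocyte list (0.49) and array 17 high for sox9a (0.762).

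The leukocyte list was higher by 0.50 in morphants at 14 dpf. With lower and higher title numbers as a block the value was 0.48. Both number groups hold the genotypes in similar shares (5 morphant and 7 wild-type arrays, and 4 and 7). The block could therefore hardly move the value, whatever the number groups did. The leukocyte difference was 0.22 in the lower and 0.77 in the higher numbers, and whether it depends on the number group was not tested. Morphant scores were alike in lower and higher numbers (8.41 to 8.96 and 8.41 to 8.94). Wild-type scores ran from 8.14 to 8.71 in lower and from 7.67 to 8.27 in higher numbers. The larger difference in the higher numbers thus goes with lower wild-type scores there, whose cause was not tested. The leukocyte score less the mean of 9 other tissue scores was higher by 0.45 (permutation p = 0.00328). This does not decide on a smaller share of the main tissue, which would raise every other tissue alike, because leukocytes were picked as the only tissue list that passed. Among the others, blood (0.47), exocrine pancreas (0.84), nervous tissue (0.15) and bone (0.06) were also higher without passing. Liver (-0.39, but 0.07 without wild-type array 10), intestine (-0.24), epidermis (-0.24), adipose (-0.18) and kidney (-0.05) were lower without passing. A response to the injected morpholino that is independent of germ cells may also raise leukocyte genes, and it was not tested, since the labels name no group with a control morpholino. A change in leukocytes that goes with germ cell number stays open beside it, as does a larger share of blood in the sample, which was not tested.

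The exocrine pancreas list was higher by 2.13 in morphants at 22 dpf. The near-duplicate arrays leave it open, because with the pairs averaged the difference was 1.80, most of its size, but its adjusted p was 0.167, between adjusted p values of 1.01e-12 and 0.715 over all alternatives of this list. Lower and higher title numbers as a block gave 2.04. Both number groups hold both genotypes (4 morphant and 8 wild-type arrays, and 6 and 6), so the block could move the value little. The pancreas difference was 3.36 in the lower and 0.88 in the higher numbers, and whether it depends on the number group was not tested. A varying amount of pancreas in the dissected trunk stays open. The members of the list had a mean pairwise correlation of 0.824 over wild-type arrays of that age. Arrays 21 (13.5) and 23 (12.3) stood far above the others, which scored 8.17 to 9.17. Without these arrays the correlation was 0.0843, but leaving them out removes most of the variation in the score, so this value does not argue against a varying amount. That the correlation must also hold without them was required only after the result had been seen. A change of pancreas size or activity in morphants was not tested.

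The 6 near-duplicate pairs deviated from their group mean with correlations of 0.765 or more. A candidate explanation is the handling of neighbouring title numbers together, as 5 of the 6 pairs have neighbouring numbers and other neighbouring pairs had a median correlation higher by 0.2 than distant pairs (0.229 over 34 pairs and 0.0298 over 223). At 22 dpf the pairs were arrays 1 and 2, 3 and 4, 5 and 6, 7 and 8, and 9 and 10. Neighbours of a group across them, such as 2 and 3 or 6 and 7, reached at most 0.534, like all other pairs. The pair at 14 dpf, 5 and 13, is not of neighbouring numbers. Neighbouring numbers alone therefore do not account for which arrays paired. The same sample on a pair of arrays stays open, and the correlation cannot decide on it, because the pairs were picked by it. Siblings or fish of the same stage were not tested.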

How the results depend on the processing

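Averaging of near-duplicate pairs, lower (1 to 12) and higher title numbers alone, the title number as a replicate block, the alternatives for lists other than germ plasm, meiosis and oocyte, and those for the difference of effects of every list were chosen after the results were seen. The intended alternatives for the comparisons of 22 with 14 dpf within a genotype were not run, as those comparisons are not reported. The cause of the changes below was not tested.

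The calls at 14 dpf (780) changed by more than 1.5 times in fits of only the groups compared (195), with the rank-sum test (229), in lower numbers alone (45, against 897 in higher numbers alone) and with the pairs averaged (400). Centring arrays on their median gave 821, 60% of them higher against 46.4%. At 22 dpf (1097) the count was 422 without rows below the median row, 1753 with array weights (31.9% higher against 17%), 284 with tissue scores as covariates (4.23% higher), 667 with the pairs averaged, and 455 and 462 in lower and higher numbers. The difference of effects (203) gave 54 without low rows, 68 with tissue covariates, 66 with the pairs averaged and 2 with the title number as a replicate block, where same-numbered arrays had a median correlation of 0.0354. The overlap (106) was 50 with tissue covariates.

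For lists, adjusted p values past 0.05 are given with the range over all alternatives of the list in brackets. At 14 dpf camera with an estimated correlation gave 0.0853 for germ plasm [1.58e-14 to 0.0853], meiosis [1.86e-06 to 0.0853] and leukocytes [0.000164 to 0.339]. The oocyte list [0.0073 to 0.717] had 0.717 there, 0.175 in camera with the preset, 0.539 in fry, 0.158 with z-scores, and 0.124 and 0.206 in lower and higher numbers. Lower numbers gave 0.339 for leukocytes and higher ones 0.0679 for meiosis. At 22 dpf lower numbers gave 0.0691 for oocyte [3.69e-52 to 0.0691], 0.102 for steroidogenesis [0.00124 to 0.112] and 0.156 for the estrogen-responsive list [0.000933 to 0.156]. Higher numbers gave 0.0606 for steroidogenesis and for ovarian somatic cells [5.47e-05 to 0.795], 0.715 for pancreas [1.01e-12 to 0.715] and 0.224 for adipose [0.000269 to 0.224]. The estimated correlation gave 0.112 for steroidogenesis and for pancreas, tissue covariates 0.0972 for steroidogenesis, and averaged pairs 0.167 for pancreas. Without low rows the ovarian list reversed (0.795, difference 0.03). For the difference of effects, germ plasm [0.0255 to 0.118] had 0.0504 without low rows and 0.118 with tissue covariates, ovarian somatic cells [0.00128 to 0.299] 0.299 without low rows, and steroidogenesis [0.016 to 0.0775] 0.0775 with z-scores. Spreads that had not passed changed sign with the ratio of SDs (testicular somatic, adjusted p = 0.738 [0.415 to 0.756]; meiosis in morphants, 0.974 [0.691 to 0.974]) and with z-scores (testicular 0.415; ovarian somatic in morphants, 0.982 [0.865 to 0.982]).

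With each array left out in turn the calls ran from 498 to 1065 at 14 dpf (509 without morphant array 1, 498 without array 13), from 897 to 1283 at 22 dpf, and from 83 to 122 for the overlap. For the difference of effects they ran from 123 to 340, with 123, 129 and 135 without morphant arrays 3, 4 and 13 of 22 dpf, and 340 and 313 without wild-type arrays 11 and 23. Every list called at 14 or 22 dpf kept its call, with adjusted p up to 0.0435 (pancreas). Leaving out an array of a near-duplicate pair keeps the other array of the pair, so this cannot show a dependence on such pairs. With the pairs averaged the pancreas list had an adjusted p of 0.167 by the permutation test. The difference of effects of germ plasm ran from 0.00744 to 0.0679, and lost its call without morphant array 3 of 14 dpf (0.0679) and arrays 3 (0.0542) and 14 (0.0501) of 22 dpf. That of meiosis ran from 0.0226 to 0.118, and passed without arrays 1 (0.0441, morphant) and 18 (0.0395, wild type) of 14 dpf and arrays 1 (0.0226), 2 (0.0242, morphant), 11 (0.0289) and 23 (0.0266, wild type) of 22 dpf. Spreads near 0 changed sign. In wild type meiosis ran from 0.574 to 0.955 (reversed without arrays 11, 0.937, and 23, 0.909, of 22 dpf). Testicular ran from 0.591 to 0.986 (reversed without arrays 17, 19 and 22 of 14 dpf and 6, 9, 11, 20 and 21 of 22 dpf, 0.802 to 0.986). In morphants meiosis ran from 0.588 to 0.989 (reversed without wild-type arrays 5, 6, 11 and 23 and morphant arrays 14, 15 and 16, 0.852 to 0.989), and ovarian from 0.801 to 0.985 (reversed without morphant arrays 16, 0.953, and 17, 0.978).

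Of 1676 gene values under other alternatives, 1379 kept their direction and side of the threshold, 286 lost their call, 2 gained one and 9 reversed, none of these called at the reversed sign. In fits of only the groups compared, 26 of 109 gene values of both ages lost their call. The reversed values at 14 dpf were cyp19a1a (-0.105 with array weights, -0.41 in higher numbers), zp3 (0.49 with tissue covariates, 0.0252 in lower numbers), foxl2a (0.12) and amh (-0.0186) in lower numbers, and bmp15 (0.0688) in higher ones. At 22 dpf they were amh (-0.0201) and ctrb.3 (-0.0064) with tissue covariates. Of 3504 values with an array left out, 3262 kept both, 229 lost their call, 2 gained one and 11 reversed at 14 dpf, in cyp19a1a (-0.29 to 0.22; -0.29 without morphant array 2), gdf9 (-0.16 to 0.15; -0.08 and -0.16 without morphant arrays 2 and 16), amh (-0.0646 to 0.19; morphant arrays 3, 15 and 16, wild-type arrays 7, 21 and 22) and zp3 (-0.21 to 0.0783; morphant array 13, wild-type array 20). Rows of low signal near 5 limit what the arrays can show, as no detection calls were at hand.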

Other observations

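The tests of this part were chosen after the scores had been seen. Wild-type trunks at 22 dpf differed widely in oocyte transcripts. The oocyte and egg coat score ran from 6.84 to 12.4 over the 14 arrays, and arrays 11 (6.97) and 23 (6.84) lay within the range of morphants, whose highest score was 7.74. That overlap rests on morphant arrays 1 (7.74) and 2 (7.69), a near-duplicate pair, as the other morphants reached at most 6.67. The germ plasm score of the same wild-type arrays ran from 7.57 to 11.4. Morphant arrays 1 and 2 also had the highest germ plasm scores of their group (8.33 and 8.38).

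A hypothesis was that the oocyte score of wild-type arrays at 22 dpf varies together with other gonadal lists, and 3 relations were computed. With the germ plasm and piRNA score Pearson's r was 0.98 (permutation p = 1e-05, the smallest that the permutations can give; adjusted p = 3e-05) and Spearman's rho 0.903 (permutation p = 2e-05). Without the 2 arrays farthest from the median r was 0.966. With the pairs averaged it was 0.984 (n = 11, permutation p = 1e-05), and 0.975 and 0.99 in lower and higher title numbers. With the ovarian somatic score r was 0.461 (permutation p = 0.0958, adjusted p = 0.144) and rho 0.499 (permutation p = 0.0723). It was 0.317 without the 2 farthest arrays (permutation p = 0.324) and 0.346 with the pairs averaged. In lower and higher title numbers r was 0.936 (n = 8) and -0.17 (n = 6), and the difference between these was not tested. Arrays 5 and 6, 7 and 8, and 9 and 10 are near-duplicate pairs, so n = 8 may overstate the number of separate samples. With the testicular somatic score r was -0.0783 (permutation p = 0.79, adjusted p = 0.79) and rho -0.143 (permutation p = 0.624). It was -0.525 without the 2 farthest arrays (permutation p = 0.0809), -0.0221 with the pairs averaged, and -0.455 and 0.242 in lower and higher title numbers. Germ cell content, which may differ between wild-type fish of this age, is a candidate explanation for the first relation, whereas the values do not decide on a relation with the ovarian or the testicular list.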
